A study of Mus musculus with 32 samples.

How the data were processed

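Gene expression was measured by RNA sequencing in bone marrow-derived dendritic cells of WT and dKO mice at 0, 1, 2 and 6 h of LPS, with 4 libraries in each of the 8 groups. Per the labels, 4 µg of total RNA, extracted with Trizol, went into each library, which was made with the TruSeq RNA kit, version 2, and the processing notes name CASAVA 1.8.2 and the mm9 genome. The labels state neither the aligner settings nor the annotation release nor how reads were assigned to genes.

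The deposited tables hold 1 library each, with 22308 entries: 22216 genes and 92 spike-in controls of the ERCC set. Each entry has a position, a gene symbol and 2 values. The first deposited value is RPKM, which the authors scaled to gene length and to a library total, with no further scaling between libraries that the values show. The second deposited value is a signal in whole numbers, read as the number of sequenced bases aligned to the gene. This reading rests on the values alone: within each gene the ratio of signal to RPKM was the same up to a constant per library (largest relative spread 4.78e-07), and small signals pile up at the length of 1 or a few reads. The signal served only for depth. A total of 9 symbols stood on 23 entries, and each entry was kept as its own gene. The annotation at hand was of a later mouse build than mm9, so positions were taken from the deposited tables and the annotation served for names alone.

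Depth was the sum of the signal over genes, 1.27 to 1.87 Gb per library. Read counts cannot be had from these tables, so no counting interval is given, and precision was taken from the spread between libraries. The spike-in controls were left out of the tests and of scaling, because their share differed between the genotypes.

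Groups came from the labels. The replicate numbers were checked for pairing by correlating the deviations of libraries from their group means: 1 of 16 pairs of a WT and a dKO library with the same number and time had a correlation above 0.1, so the numbers were not used as pairs. Across times, 16 of 24 pairs of libraries with the same number were above 0.1 within WT (median 0.14) and 5 of 24 within dKO, so libraries of a number may share a source within WT. A block on the numbers, within genotype for LPS, is an alternative. Each library was also correlated with the 4 WT group means (leaving the library itself out of its own mean). By this check 5 dKO libraries lay nearest to another time than their label gives. They were neither moved to another group nor dropped, and each count was repeated without them.

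Genes with an RPKM of at least 1 in at least 4 of the 32 libraries were tested (11154 genes). Values were log2(RPKM + 0.5). A limma model with 8 group means and an intensity trend was fitted to all 32 libraries (24 residual and 3.55 prior degrees of freedom; 19 and 5.1 without the 5 libraries), and 13 contrasts were tested: dKO against WT at each of 4 times, each of 3 LPS times against 0 h in WT and in dKO, and the difference of these LPS responses between the genotypes. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested within a contrast, and a gene was called below an adjusted p of 0.05. The targeted genes were also compared by exact permutation of the 8 libraries (70 splits).

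The 35 gene lists were 22 pathways and complexes (proteasome, antigen presentation, inflammation, interferon, metabolism, cell cycle and stress), 11 sets of cell type markers and 2 sets of genes beside the targeted genes, chosen from general knowledge. Lists with at least 3 tested members (32 of them) were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a contrast. Camera compares a list with all other genes. It was repeated with an estimated correlation, and fry was run beside it, which asks whether the members move one way on balance. Member counts are given over all genes and adjusted over the list alone. The shift of each list against all other genes was also compared over the 35 splits of the 8 libraries, a test chosen after the data were seen.

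Genes were named by a rule. It took Psmb8, Psmb9, Psmb10, Psmb5, Psmb6 and Psmb7 in the genotype comparisons, the 10 highest and 10 lowest called genes with non-overlapping groups in each genotype and WT LPS comparison, the 5 highest and 5 lowest called genes of each difference in response, and up to 4 members with the smallest adjusted p per list and comparison, with any member that a statement needs. Uncharacterised loci were passed over outside the lists. In dKO LPS comparisons only genes taken elsewhere by the rule were named. The text gives values for some of the genes so taken, leaving out most of those whose call was lost without a single library.

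The groups, contrasts, filter, test, lists, naming rule and the following alternatives were chosen before the data were examined: pseudocounts of 0.1 and 1, median-of-ratios scaling, quantile normalization, no filter, a filter at an RPKM of 5, a fit of only the compared groups, no intensity trend, array weights, a block on the replicate number, each library left out in turn, camera with an estimated correlation, and fry. The fit without the 5 libraries was chosen after the data were seen. All fits were run in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and figures were drawn in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

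The method was tested on simulated data with 11154 genes and the spread of the comparison at 0 h. With the spread as labelled, 73.1% of genes changed by 1 on the log2 scale and 98.5% of those changed by 2 were called, against 19.4% of those changed by 0.5, and 5.04% of calls were false. Without the 5 libraries these were 97.0%, 100.0%, 82.1% and 4.57%. With either spread camera called a shifted and not an unchanged list, which gives no error rate where genes correlate.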

Results

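RNA sequencing measured gene expression in dendritic cells grown from mouse bone marrow with GM-CSF, the growth factor that drives such cultures, and harvested on day 9. The cells came from wild-type (WT) C57BL/6 mice or from double-knockout (dKO) mice that lack LMP7 and MECL1, the immunoproteasome catalytic subunits encoded by Psmb8 and Psmb10. The immunoproteasome is the form of the proteasome that immune cells use to make peptides for MHC class I. Lipopolysaccharide (LPS), a bacterial cell wall component that matures dendritic cells, was given at 1 µg/mL for 0, 1, 2 or 6 h. The 2 genotypes and 4 times made 8 groups of 4 replicate libraries, 32 in all. The labels name no batch or date, and the replicate numbers did not pair WT with dKO libraries. Libraries held 1.27 to 1.87 Gb of sequence aligned to genes (mean 1.55 ± 0.142, SD, n = 32), and 9188 to 10701 genes reached 1 RPKM. The 10 most abundant genes took 13.5% to 21.3% of a library's expression. Values are RPKM, positions are on mm9, and 11154 genes were tested. Unless another spread is named, a log2 change stands with its standard error and an RPKM mean with its SD (n = 4 libraries). The p-values measure the spread between these libraries, which may be technical.

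The LPS state of 5 of the 16 dKO libraries did not match their labels. Each library was compared across genes with the 4 WT group means, and all 16 WT libraries and 11 dKO libraries correlated best with their own time. The library labelled dKO 0 h replicate 2 lay nearest to WT at 1 h, with Il6, an inflammatory cytokine, at 1124 RPKM where the other 3 libraries of its group had 0.836 to 2.04. The library labelled dKO 2 h replicate 2 lay nearest to WT at 0 h, with Il6 at 1.67 RPKM against 1154 to 1641 in the rest of its group. The libraries labelled dKO 1 h replicate 2, dKO 2 h replicate 4 and dKO 6 h replicate 4 lay nearest to WT at 2, 6 and 2 h. All 5 had Psmb8 at dKO level, 7.42 RPKM at most against at least 150.3 RPKM in every WT library. Their correlations with WT at the labelled time were 0.823 to 0.946, against 0.972 to 0.98 in the other 11 dKO libraries. All groups are given as labelled, and the number of genes called in each comparison is also given without these 5 libraries, an alternative chosen after the data were seen.

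**Figure D1:**
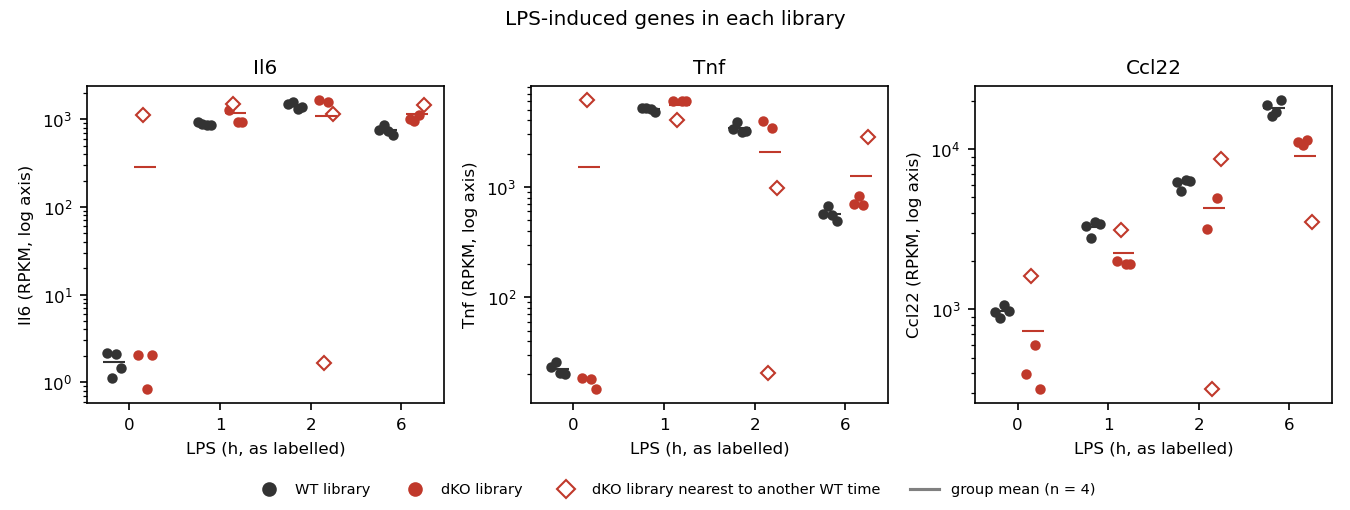
Il6, Tnf and Ccl22 in every library (RPKM, log axis) by labelled LPS time; points are libraries, lines are group means of 4, and open diamonds are the 5 dKO libraries nearest to another WT time. In the group labelled dKO 0 h, 1 library had Il6 at 1124 RPKM and the other 3 had 0.836 to 2.04 RPKM.

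The first comparison asked whether the targeted genes were reduced in the dKO cells. Psmb8 (chromosome 17, 34335140 to 34338399) was at 3.98 ± 0.281 RPKM in dKO against 193 ± 6.29 in WT at 0 h, or 2.07% of WT. It was at 2.18%, 3.09% and 1.75% of WT after 1, 2 and 6 h of LPS. Psmb10 (chromosome 8, 108459628 to 108462292) was at 5.96 ± 2.49 RPKM in dKO against 58.6 ± 2.73 in WT at 0 h, or 10.2% of WT, and then at 8.62%, 16% and 10.3% at the later times. The log2 changes at 0 h were -5.43 ± 0.12 for Psmb8 and -3.31 ± 0.28 for Psmb10 (limma adjusted p = 3.3e-23 and 7.2e-10). For both genes the 4 dKO values lay below the 4 WT values at each time, with an exact two-sided permutation p of 0.0286, the smallest that 70 splits can give. Psmb9, which encodes LMP2, the remaining immunoproteasome catalytic subunit, had 81.1 ± 14.3 against 118 ± 6.42 RPKM at 0 h and 236 ± 89.9 against 335 ± 25.8 RPKM at 6 h. Psmb9 passed the test at no time (limma adjusted p = 0.262, 0.504, 0.673 and 0.132). Without the 5 libraries Psmb9 was lower at all 4 times, by log2 changes of -0.45, -0.39, -0.46 and -0.26.

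**Figure D2:**
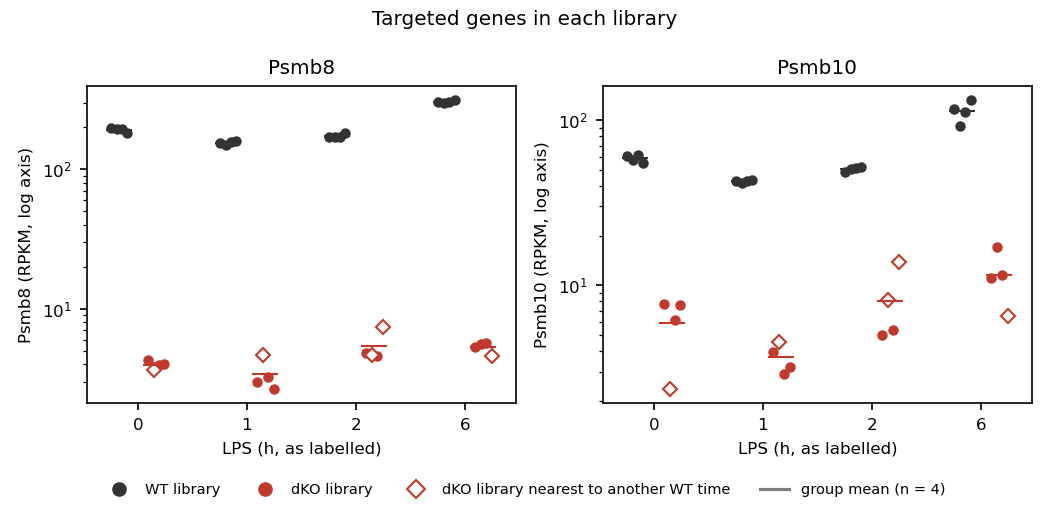
Psmb8 and Psmb10 in every library (RPKM, log axis) by labelled LPS time; points are libraries and lines are group means of 4. Every WT library had Psmb8 at 150.3 RPKM or more, and Psmb8 in dKO at 0 h averaged 3.98 RPKM.

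Among the other proteasome genes, Psmb5, which encodes the constitutive counterpart of LMP7, was lower in dKO at all 4 times. It measured 25.1 ± 6.37 against 55.5 ± 4.18 RPKM at 0 h, a log2 change of -1.17 ± 0.15 (limma adjusted p = 2.3e-06), and -1.05 ± 0.15, -0.96 ± 0.15 and -1.07 ± 0.15 at 1, 2 and 6 h. Psmb7, the counterpart of MECL1, was lower at 0 h (-0.35 ± 0.08, limma adjusted p = 0.00611) and 6 h (-0.32 ± 0.08). Psmb6, the counterpart of LMP2, had log2 changes of -0.10 ± 0.14, 0.04 ± 0.14, 0.02 ± 0.14 and 0.12 ± 0.14 and passed at no time (limma adjusted p = 0.704, 0.891, 0.939 and 0.624). As a list, the 3 immunoproteasome catalytic subunits had 2, 2, 2 and 2 members lower at 0, 1, 2 and 6 h (3, 2, 2 and 3 adjusted over the list alone). Camera called it at each time (adjusted p = 1.8e-10, 3.4e-08, 2e-07 and 8e-08), also with an estimated correlation (adjusted p = 0.00463, 0.0115, 0.0218 and 0.0255). The list holds Psmb8 and Psmb10, the targeted genes, so its call was set by the design and says nothing on untargeted subunits. The 3 constitutive catalytic subunits had 2, 1, 1 and 2 members lower (2, 1, 1 and 2 adjusted over the list alone). They shifted down as a set at 0 h (camera adjusted p = 0.00672, adjusted p = 0.101 with an estimated correlation). Of 29 other core and regulatory particle genes, 5, 0, 1 and 5 were lower (14, 0, 1 and 5 adjusted over the list alone), of which median-of-ratios scaling left 0 at 0 h and 1 at 6 h. Psma6, a core particle subunit (-0.89 ± 0.12), and Psmd4, a ubiquitin receptor of the regulatory particle (-0.31 ± 0.08), were lower at 6 h. That list shifted down at 0 h (camera adjusted p = 0.000136, adjusted p = 0.451 with an estimated correlation) and 6 h (camera adjusted p = 0.0119, adjusted p = 0.8 with an estimated correlation). Of 9 genes for the PA28 activator and proteasome assembly, 1, 1, 0 and 2 were lower (1, 2, 0 and 3 adjusted over the list alone). Psmg4, an assembly chaperone, was lower at 6 h (-0.79 ± 0.14), and the list was not called at any time (camera adjusted p = 0.255 to 0.433).

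At 0 h, before LPS, dKO cells were compared with WT cells at rest. Gdpd3, a lysophospholipase D, had 59.5 ± 7.70 against 3.60 ± 0.575 RPKM, a log2 change of 3.87 ± 0.17 (limma adjusted p = 6.2e-16). Retnla, a secreted marker of alternatively activated macrophages, was higher by 3.31 ± 0.64 (13.5 against 1.01 RPKM). Cdkn2a, which encodes cell cycle inhibitors, was higher by 2.63 ± 0.26 (9.81 against 1.19 RPKM), and H2-T10, a non-classical MHC class I gene, by 2.02 ± 0.22 (16.8 against 3.72 RPKM). Cxcl3, a neutrophil-attracting chemokine, was higher by 2.87 ± 0.67 with 1 library far above the rest (225 ± 342 against 13.9 ± 4.41 RPKM), and by 1.92 without the 5 libraries. Apart from Psmb8, the lowest were Rpl29 (0.786 ± 0.175 against 34.0 ± 2.73 RPKM) and Rpl3 (2.05 ± 0.591 against 64.9 ± 0.911 RPKM), which encode ribosomal proteins, and Tcea3, a transcription elongation factor (0.00585 ± 0.00696 against 11.1 ± 1.73 RPKM). Rnase6, an antimicrobial ribonuclease, was lower (-3.44 ± 0.27), Uchl1, a ubiquitin hydrolase (-3.37 ± 0.22), and Epcam, an adhesion molecule of Langerhans cells and epithelia (-3.12 ± 0.20). In all, 763 genes passed the test, 104 higher and 659 lower, of which 45 and 250 were at least 2-fold changed. The median log2 change of all genes was -0.19, and with median-of-ratios scaling the calls were 205 higher and 341 lower. Over all tested genes the 4 dKO and 4 WT values did not overlap in 26.5%, where chance alone gives 2.86%. With these 5 libraries left out 2920 genes passed (753 higher, 2167 lower), 761 of the 763 among them. Leaving out the library labelled dKO 0 h replicate 2 alone gave 506.

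At 1 h of LPS Gdpd3 was higher in dKO by 4.77 ± 0.17 (limma adjusted p = 3.8e-18, 56.5 against 1.56 RPKM), Retnla by 3.66 ± 0.64, and Fn1, the extracellular matrix protein fibronectin, by 2.24 ± 0.20 (744 ± 80.6 against 157 ± 15.9 RPKM). Id3, an inhibitor of basic helix-loop-helix transcription factors, was higher by 2.21 ± 0.52, and Ppp1r3b, a glycogen-targeting phosphatase subunit, by 2.14 ± 0.37. Rpl3 was lower (-5.26 ± 0.22) and Rpl29 (-4.51 ± 0.17). Also lower were Cd300e, an activating receptor of myeloid cells (-3.65 ± 0.23, 0.326 against 9.89 RPKM), and Cldn1, a tight junction protein (-3.42 ± 0.32, 3.06 against 36.4 RPKM). The test passed 1211 genes, 205 higher and 1006 lower (71 and 378 at least 2-fold), with the median of all genes at -0.18. Median-of-ratios scaling gave 474 higher and 693 lower. In 32.1% of all tested genes the groups did not overlap (2.86% by chance). Leaving out the 5 libraries gave 4368 genes, 1093 higher and 3275 lower, and kept 1210 of the 1211.

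At 2 h the group labelled dKO held 2 of the 5 libraries. Gdpd3 (5.13 ± 0.17, limma adjusted p = 7.2e-19), Retnla (3.02 ± 0.64), Orm2, an acute-phase protein (2.26 ± 0.23), and Aqp3, a water and glycerol channel (1.95 ± 0.29), were higher. Cd207, which encodes langerin, a lectin of Langerhans cells and some dendritic cells, was lower (-3.57 ± 0.30, 0.134 against 7.40 RPKM). Stfa2, a cysteine protease inhibitor, was lower (-3.29 ± 0.35) and Gdf15, a stress-induced cytokine (-3.29 ± 0.36, 3.41 against 36.6 RPKM). Ifna4, a type I interferon, was lower (-3.25 ± 0.84), and stood at -1.29 without the 5 libraries. The test passed 1381 genes, 574 higher and 807 lower (160 and 325 at least 2-fold), around a median of 0.09, but quantile normalization gave 1136 higher and 973 lower. The groups did not overlap in 13.4% of all tested genes (2.86% by chance), the lowest share of the 4 times. With the 5 libraries left out, 3689 genes passed (1036 higher, 2653 lower), and 1205 of the 1381 were among them. Leaving out the library labelled dKO 2 h replicate 3 alone gave 2247 genes.

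After 6 h of LPS, Arg1, the arginase of alternatively activated macrophages, was higher in dKO by 3.10 ± 0.43 (84.4 ± 64.9 against 7.6 ± 2.22 RPKM, limma adjusted p = 6.7e-06). Ctsl, the lysosomal protease cathepsin L, was higher by 2.05 ± 0.15 (367 ± 25.7 against 90.0 ± 20.3 RPKM), Pmp22, a membrane protein, by 2.30 ± 0.22, and Gdpd3 by 4.99 ± 0.17. Rpl3 was lower (-5.23 ± 0.22), Cd207 (-3.29 ± 0.30), Anxa8, an annexin (-3.0 ± 0.18) and Extl1, a glycosyltransferase (-2.70 ± 0.13). Tcea3 was listed at 0 in all 4 dKO libraries and at 6.33 ± 1.03 RPKM in WT. Here 1649 genes passed, 507 higher and 1142 lower (162 and 313 at least 2-fold), around a median of -0.15, but with median-of-ratios scaling 923 were higher and 882 lower. The groups did not overlap in 31.1% of all tested genes (2.86% by chance). The count without the 5 libraries was 5233 (1555 higher, 3678 lower), 1647 of the 1649 among them. Leaving out WT 6 h replicate 4 alone gave 1093.

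Across the 4 times, 307 genes were called in the same direction at each, 60 higher and 247 lower, where independent calls would give 0.00447 higher and 0.44 lower. The 4 times share the genotypes and perhaps the mice, so they are not independent tests. Of the 307, 175 had a mean change of at least 2-fold, 42 higher and 133 lower. Gdpd3, Retnla, Fn1, H2-T10 and Ctsl were among the higher ones, and Rpl3, Rpl29, Tcea3, Uchl1 and Akr1e1, an aldo-keto reductase, among the lower ones. The fit without the 5 libraries called 1270 genes at all 4 times (321 higher, 949 lower), 305 of the 307 among them.

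Of 28 lysosomal and phagocytic genes measured, 3, 7, 10 and 15 were higher in dKO at 0, 1, 2 and 6 h (6, 11, 10 and 15 adjusted over the list alone) and 1 was lower at each time (1, 2, 1 and 1 adjusted over the list alone). Camera gave adjusted p = 4.2e-07, 1.2e-10, 8.2e-05 and 5.7e-15, and adjusted p = 0.209, 0.0663, 0.289 and 0.0255 with an estimated correlation, so the latter call held at 6 h alone. Macrophage markers, which share Fcgr1, Mertk and Gpnmb with this list, were also called up at 1 and 6 h (below), so the shift may come with them. At 6 h Gla, a lysosomal galactosidase, was higher by 1.18 ± 0.12, and Ctsb, cathepsin B, by 0.77 ± 0.10 (652 ± 55.1 against 382 ± 33.4 RPKM). Ctsk, cathepsin K, was lower at 0 h (-1.86 ± 0.24, 9.11 ± 1.69 against 34.4 ± 5.62 RPKM). Of 22 glycolysis genes and HIF-1 targets, 1, 2, 9 and 11 were higher (1, 3, 10 and 13 adjusted over the list alone) and none lower at any time (limma). Their camera adjusted p was 0.000136, 4.3e-05, 0.000106 and 5.2e-11, and 0.404, 0.244, 0.289 and 0.072 with an estimated correlation. Hif1a itself, the oxygen-regulated transcription factor, was higher by 1.25 ± 0.15 at 6 h and Hk2, hexokinase, by 0.95 ± 0.15. The glucose transporter Slc2a1 was higher by 1.18 ± 0.24. For both lists no other of the 35 splits of the 8 libraries gave as large a shift against all other genes at any time (exact permutation p of 0.0286, the smallest possible), a test added after the data were seen.

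Of 28 cell cycle genes, 10, 18, 6 and 3 were lower in dKO at 0, 1, 2 and 6 h (25, 24, 12 and 3 adjusted over the list alone) and none higher by limma. The median log2 change of the list was -0.89 at 0 h and -1.01 at 1 h. The camera adjusted p was 1.2e-08, 8.3e-09, 1.1e-07 and 0.395, and 0.404, 0.251, 0.289 and 0.949 with an estimated correlation. Mcm5, of the replicative helicase, was lower at 0 h (-1.04 ± 0.22, 6.73 against 13.9 RPKM). At 1 h Mcm6, of the same helicase (-1.18 ± 0.26), Rrm1, of ribonucleotide reductase (-1.04 ± 0.23), and Bub1, a spindle checkpoint kinase (-1.01 ± 0.23), were lower. Leaving out the 5 libraries, 28, 28, 22 and 19 members were lower. Of 21 cholesterol synthesis genes, 3, 5, 4 and 3 were lower and 0, 0, 0 and 2 were higher (5, 8, 4 and 3 lower adjusted over the list alone). That list had camera adjusted p = 0.0058, 0.00447, 0.00426 and 0.945, and adjusted p = 0.472, 0.59, 0.447 and 0.987 with an estimated correlation. The 33 respiratory chain genes had 1, 1, 1 and 2 lower (1, 1, 1 and 0 adjusted over the list alone), or 2 higher and 1 lower at 1 and at 6 h with median-of-ratios scaling. That list was not called (camera adjusted p = 0.313 to 0.638).

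Among antigen presentation genes, H2-T22 was lower at 0 h (-2.45 ± 0.32, limma adjusted p = 3.6e-06) while H2-T10, another non-classical class I gene, was higher. Exchange of reads between them was not tested. Of 17 MHC class I presentation genes 1 was higher at each time, and 2, 1, 1 and 2 were lower (4, 1, 1 and 2 adjusted over the list alone), but 3 higher and 1 lower at 6 h with median-of-ratios scaling. The list was not called (camera adjusted p = 0.435 to 0.968). Of 13 MHC class II presentation genes 4, 4, 4 and 4 were lower and 0, 0, 1 and 1 higher (4, 4, 6 and 4 and 0, 0, 1 and 2 adjusted over the list alone), but 3 higher and 2 lower at 6 h with median-of-ratios scaling. The class II list was called at 2 h (camera adjusted p = 0.00273, adjusted p = 0.289 with an estimated correlation). At 0 h H2-DMb2, a peptide-loading chaperone (-0.75 ± 0.12, 115 ± 15.6 against 193 ± 18.5 RPKM), and H2-Ob (-0.70 ± 0.14) were lower, and they lie beside Psmb8 on chromosome 17. Of 28 measured genes next to Psmb8, 4, 4, 4 and 4 were lower (4, 5, 4 and 4 adjusted over the list alone) and 1 was higher at 2 h (1 adjusted over the list alone). They were called as a list at 2 h (camera adjusted p = 0.0301, adjusted p = 0.378 with an estimated correlation). Of 26 genes next to Psmb10, 3, 1, 2 and 2 were lower and 0, 1, 0 and 0 higher (the same adjusted over the list alone), and the list was never called (camera adjusted p = 0.266 to 0.756).

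Of 20 costimulation and dendritic cell maturation genes, 2, 3, 4 and 3 were lower (2, 6, 5 and 3 adjusted over the list alone). At 2 h they were called (camera adjusted p = 2.7e-05, adjusted p = 0.378 with an estimated correlation), with Slamf1, a lymphocyte and dendritic cell receptor, lower (-2.05 ± 0.43 as labelled, -1.45 without the 5 libraries). Inflammatory cytokines, chemokines, NF-kappaB members and immediate early genes shifted up at 0 h (camera adjusted p = 3e-05, 5.7e-06, 0.00157 and 0.000779 in that order, and adjusted p = 0.451, 0.445, 0.525 and 0.451 with an estimated correlation). At 2 h cytokines, chemokines, NF-kappaB members and type I interferon response genes shifted down (camera adjusted p = 0.000297, 0.0106, 7.2e-05 and 0.000339 in that order, and adjusted p = 0.447, 0.66, 0.447 and 0.66 with an estimated correlation). Few members passed over the 4 times. Of 19 cytokines none was higher by limma and 1, 0, 1 and 1 were lower, with 2, 1, 7 and 3 at unadjusted p below 0.05. Of 18 chemokines 2, 2, 1 and 1 were higher and 0, 0, 2 and 1 lower, and of 22 NF-kappaB members 0, 0, 1 and 0 were higher and 0, 0, 4 and 1 lower. Of 25 immediate early genes 0, 0, 1 and 0 were higher and 1, 3, 4 and 0 lower, and of 38 interferon response genes 3, 0, 0 and 0 were lower. Adjusted over the list alone, NF-kappaB members had 9 lower at 2 h, chemokines 3 higher at 0 h and 1 lower at 0 and 1 h, immediate early genes 1 higher at 1 h, and the other counts were the same. The libraries labelled dKO 0 h replicate 2, which looked stimulated, and dKO 2 h replicate 2, which looked unstimulated, lie in these groups. With the 5 libraries left out none of the cytokine, chemokine and immediate early lists was called at 0 h (camera adjusted p = 0.607 to 0.807), and NF-kappaB members at 0 h and chemokines at 2 h turned direction. Chemokines were also called up at 1 h (camera adjusted p = 0.00501, adjusted p = 0.693 with an estimated correlation).

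Of 18 interferon regulatory factors and STATs 2, 4, 6 and 4 were lower (4, 5, 6 and 5 adjusted over the list alone). At 0 h Batf3, which specifies cross-presenting dendritic cells (-1.08 ± 0.14), and Stat4 (-1.48 ± 0.24) were lower, and at 2 h the list was called (camera adjusted p = 0.000491, adjusted p = 0.289 with an estimated correlation). Toll-like receptor signalling genes had 0, 1, 4 and 5 of 27 higher and 1, 1, 1 and 2 lower (the same adjusted over the list alone), or 1 higher and 0 lower at 0 h with median-of-ratios scaling. As a list they shifted up at 0, 1 and 6 h (camera adjusted p = 0.0111, 0.0138 and 0.0166), with adjusted p = 0.365, 0.244 and 0.248 with an estimated correlation, although the list median was -0.01 at 1 h. NRF2 targets shifted up at 0 and 1 h (camera adjusted p = 0.0237 and 0.0319, adjusted p = 0.472 and 0.59 with an estimated correlation), although the median of the list was -0.04 at 1 h. Of its 19 members 1, 3, 2 and 3 were higher and 1, 1, 1 and 1 lower (1, 3, 2 and 3 and 1, 1, 2 and 1 adjusted over the list alone). Unfolded protein response genes had 3, 2, 1 and 2 of 20 lower and 0, 0, 1 and 1 higher, or 3 higher and 1 lower at 6 h with median-of-ratios scaling. Heat shock and ubiquitin genes had 1, 1, 3 and 3 of 17 lower and 0, 0, 3 and 0 higher. Both had the same counts adjusted over the list alone, and neither list was called (camera adjusted p = 0.355 to 0.803).

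**Figure D3:**
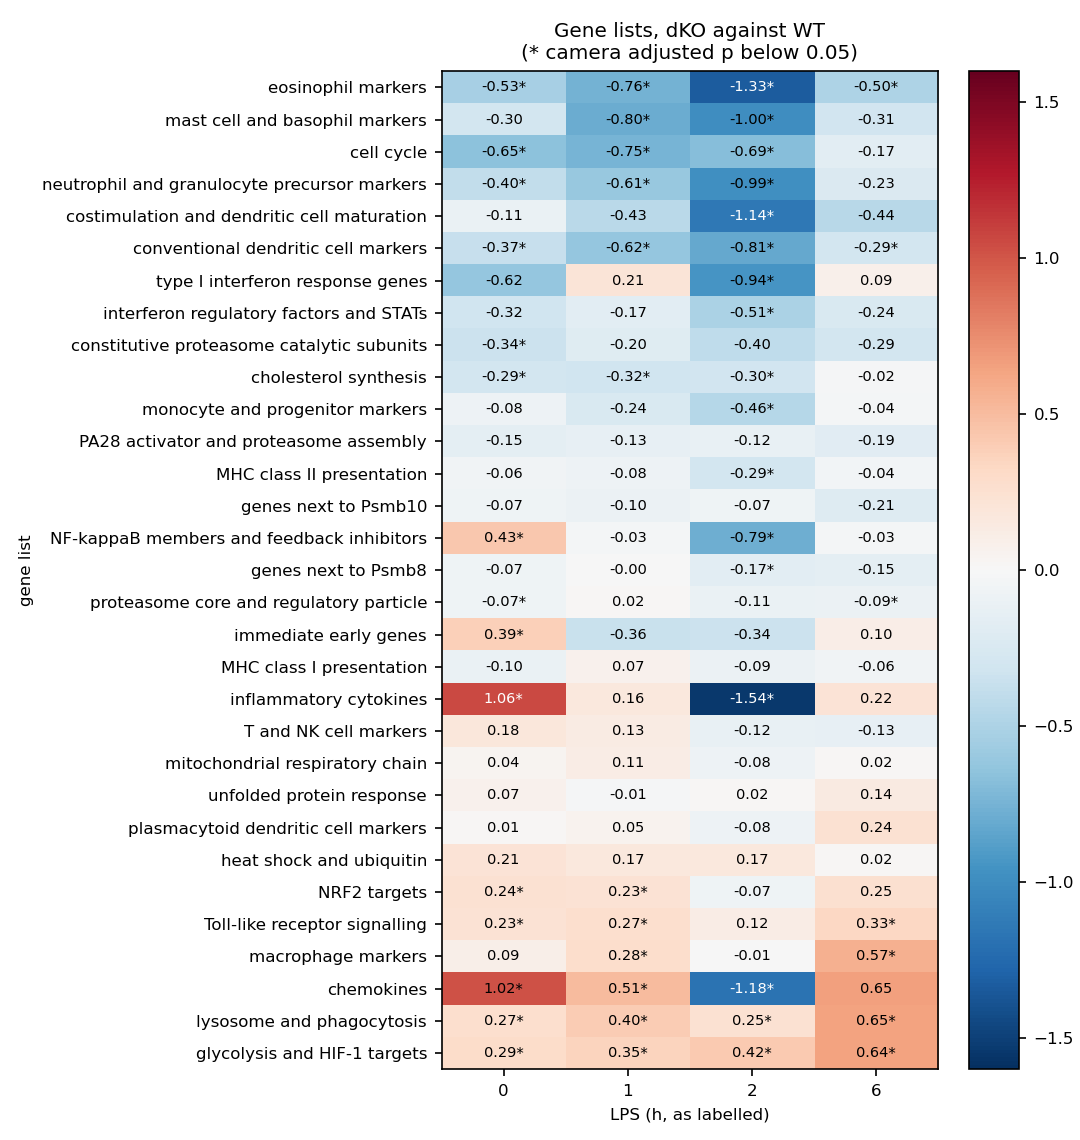
Mean log2 change of each gene list minus that of all other genes, dKO against WT, at each labelled LPS time, without the immunoproteasome list; stars are camera calls. The lysosome list was called higher at all 4 times (0.27, 0.40, 0.25 and 0.65), with adjusted p = 0.209, 0.0663, 0.289 and 0.0255 with an estimated correlation.

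Markers of other cells that such cultures hold differed as well. Of 14 conventional dendritic cell markers, 5, 8, 9 and 7 were lower (8, 9, 9 and 7 adjusted over the list alone). Their camera adjusted p was 0.0063, 1.9e-05, 1.4e-07 and 0.0255, and adjusted p = 0.0868, 0.00257, 0.00025 and 0.0821 with an estimated correlation. Cd209a, a dendritic cell lectin, had 3.13 ± 1.28 against 15.5 ± 3.73 RPKM at 0 h (-2.17 ± 0.35), and Zbtb46, a transcription factor of conventional dendritic cells, was lower at 2 h (-0.99 ± 0.17). Macrophage markers split. Pf4 (1.39 ± 0.22, 144 ± 27.9 against 54.9 ± 11.6 RPKM) and Apoe (1.00 ± 0.23) were higher at 0 h, and the complement genes C1qb (-2.36 ± 0.30, 95.2 ± 32.4 against 471 ± 75.9 RPKM) and C1qc (-1.48 ± 0.32) were lower. Of 16 markers, 2, 4, 4 and 6 were higher and 3, 3, 3 and 1 lower (3, 4, 4 and 6 and 5, 3, 3 and 1 adjusted over the list alone, 3 higher and 2 lower at 0 h with median-of-ratios scaling). Camera called this list up at 1 h (camera adjusted p = 0.00314, adjusted p = 0.244 with an estimated correlation) and 6 h (camera adjusted p = 0.000116, adjusted p = 0.129 with an estimated correlation). Of 15 neutrophil and precursor markers, 5, 7, 9 and 6 were lower and 0, 1, 0 and 1 were higher (7, 9, 10 and 7 and 1, 1, 1 and 1 adjusted over the list alone). Camera gave adjusted p = 0.0122, 0.000186, 2.4e-08 and 0.266, and adjusted p = 0.451, 0.244, 0.0378 and 0.842 with an estimated correlation. S100a8 (88.7 ± 22.5 against 238 ± 23.9 RPKM) and S100a9 (118 ± 41.0 against 309 ± 41.9 RPKM), calcium-binding proteins of granulocytes and monocytes, were lower at 0 h, and Mmp8, neutrophil collagenase, was higher at 6 h by 1.62 ± 0.29. Of 8 eosinophil markers, 3, 5, 6 and 4 were lower (5, 6, 6 and 5 adjusted over the list alone). This list had camera adjusted p = 0.0058, 0.000482, 5.4e-08 and 0.0492, and adjusted p = 0.442, 0.244, 0.0378 and 0.731 with an estimated correlation. Ear1, an eosinophil ribonuclease, had 33.7 ± 2.00 against 122 ± 18.9 RPKM at 1 h.

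Of 8 mast cell and basophil markers, 3, 4, 7 and 0 were lower (3, 7, 7 and 0 adjusted over the list alone), among them Cpa3, mast cell carboxypeptidase, at 1 h (-1.44 ± 0.26). These were called at 1 h (camera adjusted p = 0.000186, adjusted p = 0.116 with an estimated correlation) and 2 h (camera adjusted p = 1.3e-05, adjusted p = 0.0378 with an estimated correlation). Of 12 monocyte and progenitor markers, 2, 3, 2 and 1 were lower and 0, 0, 0 and 1 higher (3, 3, 3 and 3 and 0, 0, 0 and 1 adjusted over the list alone). The monocyte list was called at 2 h (camera adjusted p = 0.0208, adjusted p = 0.0701 with an estimated correlation). T and NK cell markers had 0, 1, 0 and 1 of 4 lower, or 1 higher and 0 lower at 1 and at 6 h with quantile normalization. Plasmacytoid dendritic cell markers had 1 of 6 lower at each time. Both had the same counts adjusted over the list alone and neither list was called (camera adjusted p = 0.28 to 0.99). The B cell, erythroid and fibroblast lists had 2, 1 and 1 measured members and were not tested as lists. Sdc1, syndecan, was higher at 0 h by 1.48 ± 0.28 and Blk, a B cell kinase, lower (-0.92 ± 0.19). Car2, carbonic anhydrase, had a log2 change of -0.32 at 0 h that did not pass, and Fn1 was higher at 0 h by 1.83 ± 0.20 (739 ± 191 against 205 ± 36.5 RPKM).

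The comparison with other splits was run on every tested list. Of the lists called by camera between dKO and WT, 9 of 16, 11 of 13, 11 of 18 and 6 of 8 had a shift that no other split reached at 0, 1, 2 and 6 h. The rest were reached. At 0 h these were cytokines and NF-kappaB members (in 32 of 35 splits each, the real one included), immediate early genes (26), chemokines (22), neutrophil markers (5), eosinophil markers (4) and proteasome core genes (2). At 1 h these were macrophage (3) and neutrophil markers (2). At 2 h they were chemokines (26), interferon response genes (23), interferon regulatory factors (14), costimulation genes (6), MHC class II genes (5), cholesterol synthesis (3) and the neighbours of Psmb8 (2), and at 6 h conventional dendritic cell markers (4) and proteasome core genes (3). Those shifts may come from the spread between libraries. For LPS in WT 13 of 15, 13 of 13 and 15 of 15 called lists were reached by no other split, the exceptions at 1 h being proteasome core genes (30) and the respiratory chain (4). For LPS in dKO these were 5 of 13, 1 of 15 and 11 of 13.

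The second set of comparisons asked how LPS changed WT cells. After 1 h Ifnb1, interferon beta, went from 0.336 ± 0.147 to 611 ± 42.9 RPKM (log2 change 9.53 ± 1.73, limma adjusted p = 0.000245), and Tnf from 22.4 ± 2.71 to 5032 ± 213 RPKM (7.78 ± 1.31). Il6 rose by 8.69 ± 1.54 (885 ± 37.3 against 1.70 ± 0.503 RPKM), Il12b, a shared interleukin subunit, by 7.99 ± 1.58, and Ptgs2, the inducible cyclooxygenase, by 7.35 ± 1.35. Gpr146, an orphan receptor, fell from 24.2 to 1.36 RPKM (-3.74 ± 0.66). S1pr2, a sphingosine phosphate receptor (-3.54 ± 0.47), and Dusp6, a phosphatase of ERK (-3.26 ± 0.52), also fell. Of 19 inflammatory cytokines 16 rose, as did 20 of 22 NF-kappaB members and feedback inhibitors, 15 of 18 chemokines and 16 of 25 immediate early genes. Their camera adjusted p was 2.9e-24, 5.4e-26, 5.1e-20 and 1.1e-23, and 0.0206, 0.0206, 0.0275 and 0.00874 with an estimated correlation. Adjusted over the list alone 16, 20, 16 and 17 rose. In the latter 3 lists 1 gene each fell (1 adjusted over the list alone). Nr4a1 (5.08 ± 0.72) and Dusp2 (5.44 ± 0.72) were among the immediate early genes. Of 20 costimulation genes, 14 rose (14 adjusted over the list alone, camera adjusted p = 2.7e-17, adjusted p = 0.0402 with an estimated correlation). In all 763 genes rose and 5074 fell (423 and 1357 at least 2-fold), around a median of -0.42, but with median-of-ratios scaling 1681 rose and 1470 fell. In 75.3% of all tested genes the groups did not overlap (2.86% by chance). Without the dKO libraries in doubt, which add to the common variance and so to standard errors of LPS changes, 1222 rose and 7666 fell.

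Interferon response genes followed at 2 h. Of 38 genes, 7, 33 and 37 rose and 2, 0 and 0 fell at 1, 2 and 6 h (7, 33 and 38 and 1, 0 and 0 adjusted over the list alone, list median -0.24 at 1 h). Camera called them at each time (adjusted p = 2.7e-05, 1.3e-24 and 2.8e-24), with adjusted p = 0.656, 0.0967 and 0.152 with an estimated correlation. Rsad2, viperin, went from 4.57 ± 0.314 to 1511 ± 108 RPKM at 2 h (8.22 ± 1.45, limma adjusted p = 2.2e-05). Cxcl10, an interferon-induced chemokine, reached 3298 ± 138 RPKM (9.12 ± 1.58). Il12b rose by 9.30 ± 1.58 and Ccl4, a chemokine of macrophages, by 7.92 ± 1.26 (6930.0 ± 587 against 28.3 ± 4.30 RPKM). Of the immediate early genes 7 were above 0 h and 7 were below it (the same adjusted over the list alone, camera adjusted p = 0.000191, adjusted p = 0.279 with an estimated correlation). Egr2 (-3.64 ± 0.57) and Myc (-2.98 ± 0.47) were among the lower ones. Cebpa, a transcription factor of myeloid differentiation, fell by a log2 change of -3.96 ± 0.63. Of 18 interferon regulatory factors and STATs, 4, 10 and 13 rose and 0, 5 and 1 fell (the same adjusted over the list alone) over the 3 times. They were called at each (camera adjusted p = 0.00177, 9.9e-07 and 1.2e-08, and 0.291, 0.089 and 0.152 with an estimated correlation). Above 0 h stood 17 of 19 cytokines, 17 of 18 chemokines, 19 of 22 NF-kappaB members and 15 of 20 costimulation genes, and 0, 1, 1 and 1 were below it (the same adjusted over the list alone). Their camera adjusted p was 2.4e-19, 3e-18, 1.6e-18 and 4.7e-15, and 0.0715, 0.0715, 0.0715 and 0.0802 with an estimated correlation. At 2 h 1253 genes rose and 7640 fell (700 and 3981 at least 2-fold) around a median of -0.73. Under median-of-ratios scaling 3427 rose and 3464 fell. In 85.5% of all tested genes the groups did not overlap (2.86% by chance). Leaving out the 5 dKO libraries, 1594 rose and 8357 fell.

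By 6 h Il12b reached 3151 ± 163 against 3.43 ± 0.572 RPKM (9.66 ± 1.58, limma adjusted p = 6.2e-06) and Ccl22, a chemokine of mature dendritic cells, 18098 against 972 RPKM (4.22 ± 0.59). All 3 immunoproteasome genes rose (3 adjusted over the list alone, camera adjusted p = 0.00323, adjusted p = 0.152 with an estimated correlation), Psmb9 by 1.5 ± 0.27 (335 ± 25.8 against 118 ± 6.42 RPKM), Psmb10 by 0.93 ± 0.28 and Psmb8 by 0.66 ± 0.12. Of 17 MHC class I presentation genes, 0, 4 and 13 rose and 4, 4 and 3 fell (the same adjusted over the list alone), or 1 higher and 0 lower at 1 h with median-of-ratios scaling. The class I list was called at 2 h (camera adjusted p = 0.00319, adjusted p = 0.397 with an estimated correlation) and 6 h (camera adjusted p = 6.8e-06, adjusted p = 0.181 with an estimated correlation). Of 20 costimulation genes, 17 rose (camera adjusted p = 2.6e-14, adjusted p = 0.152 with an estimated correlation). Also above 0 h were 18 of 19 cytokines, 17 of 18 chemokines and 20 of 22 NF-kappaB members. Their camera adjusted p was 7.6e-13, 1.7e-10 and 2.6e-13, and 0.152 each with an estimated correlation. Of these, 1 chemokine and 1 NF-kappaB member fell. Costimulation genes and these 3 lists had the same counts adjusted over the list alone. Scd2, a fatty acid desaturase (-4.43 ± 0.57, 12.0 ± 1.32 against 268 ± 18.8 RPKM), Fads1 (-4.32 ± 0.45) and Ccr2, a chemokine receptor of monocytes (-4.28 ± 0.79), were among the genes that fell most. At 6 h 1662 genes rose and 6795 fell (926 and 3824 at least 2-fold), around a median of -0.65. Here median-of-ratios scaling had 3636 rise and 3772 fall. In 84.6% of all tested genes the groups did not overlap (2.86% by chance). The fit without the 5 libraries had 2072 rise and 7760 fall.

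Of 28 cell cycle genes, 7, 24 and 25 fell and 1, 0 and 1 rose at 1, 2 and 6 h (6, 24 and 25 and 1, 0 and 1 adjusted over the list alone), and 23 fell at 6 h with median-of-ratios scaling. They were called at 6 h (camera adjusted p = 5.7e-05, adjusted p = 0.484 with an estimated correlation), and Ccna2, cyclin A, fell (-3.23 ± 0.35). Of 21 cholesterol synthesis genes, 9, 14 and 19 fell and 3, 1 and 2 rose (the same adjusted over the list alone), but with median-of-ratios scaling 4 rose and 2 fell at 1 h and 15 fell at 6 h. The list was called at 6 h (camera adjusted p = 0.0206, adjusted p = 0.552 with an estimated correlation), when Dhcr7, a reductase of the pathway, fell (-4.26 ± 0.52). Of 28 lysosomal genes, 18, 17 and 21 fell and 0, 0 and 4 rose (the same adjusted over the list alone), but with median-of-ratios scaling 2 rose and 0 fell at 1 h and 12 and 3 at 2 h. Camera called them at 6 h (camera adjusted p = 0.044, adjusted p = 0.552 with an estimated correlation). Of 33 respiratory chain genes, 28, 31 and 30 fell (30, 31 and 30 adjusted over the list alone), but with median-of-ratios scaling 1, 16 and 8 rose and 1, 1 and 9 fell. This list was called at 1 h (camera adjusted p = 0.0117, adjusted p = 0.815 with an estimated correlation) and 6 h (camera adjusted p = 0.00614, adjusted p = 0.628 with an estimated correlation). Of 29 proteasome core and regulatory genes, 24, 19 and 17 fell and 1, 1 and 5 rose (the same adjusted over the list alone), but with median-of-ratios scaling 1, 20 and 18 rose and 1, 0 and 1 fell. Their call was at 1 h (camera adjusted p = 0.0132, adjusted p = 0.656 with an estimated correlation). Of 22 glycolysis genes, 3, 12 and 16 fell and 1, 2 and 1 rose (2, 11 and 16 and 1, 2 and 1 adjusted over the list alone), but with median-of-ratios scaling 2 rose and 1 fell at 1 h and 9 rose and 5 fell at 2 h. Glycolysis was not called (camera adjusted p = 0.0633 to 0.801).

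Of 27 Toll-like receptor signalling genes, 6, 11 and 12 rose and 8, 10 and 7 fell (the same adjusted over the list alone), or 11 higher and 4 lower at 1 h with median-of-ratios scaling. They shifted up at each time (camera adjusted p = 0.00292, 0.000493 and 0.0002, and 0.0854, 0.0715 and 0.152 with an estimated correlation). Cd14, the LPS co-receptor, rose by 3.36 ± 0.58 at 1 h, and Tlr4, the LPS receptor, fell at 6 h (-2.49 ± 0.26). Heat shock and ubiquitin genes were called up at 6 h (camera adjusted p = 0.0355, adjusted p = 0.152 with an estimated correlation), with 7 of 17 higher and 7 lower (the same adjusted over the list alone, list median -0.06). Of 13 MHC class II genes 4, 5 and 7 fell and 0, 3 and 1 rose (3, 5 and 7 and 0, 3 and 1 adjusted over the list alone), but with median-of-ratios scaling 8, 9 and 6 rose and 1, 1 and 3 fell. Of 9 PA28 and assembly genes 5, 5 and 4 fell and 0, 0 and 4 rose, but with median-of-ratios scaling 2 h had 4 higher and 3 lower, and of 3 constitutive catalytic subunits 2, 1 and 1 fell and 0, 1 and 1 rose. Of 20 unfolded protein response genes 12, 14 and 13 fell and 1, 4 and 2 rose, but with median-of-ratios scaling 5 rose and 4 fell at 1 h and 6 rose and 4 fell at 2 h. Of 19 NRF2 targets 7, 11 and 12 fell and 3, 5 and 3 rose, but with median-of-ratios scaling 3 rose and 0 fell at 1 h and 7 rose and 2 fell at 2 h. These 4 lists had the same counts adjusted over the list alone. None of these 5 lists was called (camera adjusted p = 0.119 to 0.951).

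Among cell type lists, 8, 8 and 5 of 15 neutrophil markers rose and 0, 3 and 6 fell (9, 8 and 4 and 0, 3 and 6 adjusted over the list alone), but with median-of-ratios scaling 6 rose and 5 fell at 6 h. They were called up at 1 h (camera adjusted p = 4e-08, adjusted p = 0.0349 with an estimated correlation) and 2 h (camera adjusted p = 2.1e-05, adjusted p = 0.0967 with an estimated correlation). Of 8 mast cell and basophil markers, 7, 6 and 2 rose and 0, 0 and 1 fell (7, 5 and 2 and 0, 0 and 1 adjusted over the list alone). Camera called these at each time (adjusted p = 6.9e-10, 1.4e-05 and 0.00622, and 0.00874, 0.0715 and 0.181 with an estimated correlation). Of 8 eosinophil markers, 4, 4 and 2 rose and 1, 1 and 3 fell (6, 4 and 2 and 1, 1 and 3 adjusted over the list alone), but with median-of-ratios scaling 5 rose and 2 fell at 6 h. Eosinophil markers were called up at 1 h (camera adjusted p = 3.3e-05, adjusted p = 0.0828 with an estimated correlation) and 2 h (camera adjusted p = 0.000493, adjusted p = 0.138 with an estimated correlation). Of 14 conventional dendritic cell markers, 4, 4 and 4 rose and 1, 5 and 6 fell (3, 4 and 4 and 1, 4 and 6 adjusted over the list alone), but with median-of-ratios scaling 5 rose and 0 fell at 2 h and 7 rose and 6 fell at 6 h. As a list they were called up at 1 h (camera adjusted p = 0.000454, adjusted p = 0.00874 with an estimated correlation) and 2 h (camera adjusted p = 0.0159, adjusted p = 0.0715 with an estimated correlation), although the list medians were -0.06 and -0.46. Cd209a fell at 6 h (-3.25 ± 0.35). Of 12 monocyte markers, 1, 2 and 3 rose and 1, 5 and 5 fell (1, 2 and 3 and 0, 5 and 5 adjusted over the list alone), but with median-of-ratios scaling 5 rose and 1 fell at 2 h and 5 rose and 4 fell at 6 h. Their list was called up at 1 h (camera adjusted p = 0.00636, adjusted p = 0.0217 with an estimated correlation). Of 16 macrophage markers, 4, 7 and 12 fell and 1, 1 and 2 rose (3, 7 and 12 and 1, 1 and 2 adjusted over the list alone), but with median-of-ratios scaling 2 rose and 1 fell at 1 h and 5 rose and 2 fell at 2 h, with no call (camera adjusted p = 0.279 to 0.836). Csf1r, the macrophage growth factor receptor (-3.80 ± 0.41), and Lyz2, lysozyme (-2.28 ± 0.26), fell at 6 h.

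Of 4 T and NK cell markers 0, 2 and 2 rose and 1, 1 and 1 fell (0, 2 and 2 and 0, 1 and 1 adjusted over the list alone). Of 6 plasmacytoid markers 0, 2 and 1 rose and 1, 2 and 4 fell (0, 2 and 1 and 0, 2 and 4 adjusted over the list alone), but with quantile normalization 2 rose and 0 fell at 1 h and 2 rose and 1 fell at 6 h. Of 28 neighbours of Psmb8 0, 6 and 8 rose and 11, 14 and 15 fell (the same adjusted over the list alone), but with median-of-ratios scaling 9, 14 and 13 rose and 3, 5 and 6 fell. Of 26 neighbours of Psmb10 2, 1 and 1 rose and 14, 21 and 20 fell (2, 1 and 1 and 18, 21 and 20 adjusted over the list alone), and none of the 4 lists was called (camera adjusted p = 0.0934 to 0.689). Outside the tested lists 0, 0 and 2 of 2 B cell genes fell, Car2 rose at 1 and 2 h and Fn1 fell at 6 h. A marker that rises after LPS need not come from more cells, so these lists do not count cells here.

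**Figure D4:**
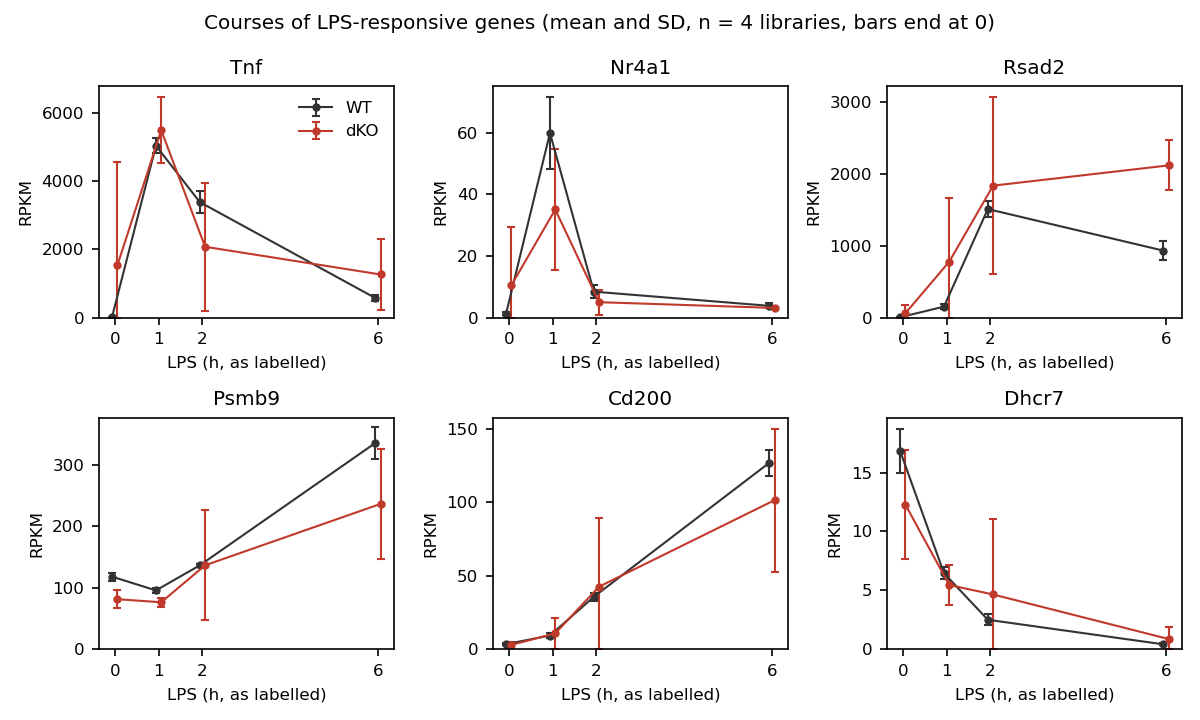
Mean RPKM (with SD, n = 4 libraries) of 6 genes at 0, 1, 2 and 6 h of LPS in WT and dKO as labelled. Tnf rose in WT from 22.4 to 5032 RPKM at 1 h, and its mean of the group labelled dKO 0 h includes a library with 6060 RPKM.

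The same questions were asked of dKO cells, whose groups hold the 5 libraries. At 1 h Tnf rose by 6.16 ± 1.31 as labelled (limma adjusted p = 0.00496) and by 8.41 without the 5 libraries, and Cxcl1, a neutrophil chemoattractant, by 6.49 ± 1.42 and 8.82. Of the lists, 15 of 19 cytokines, 15 of 18 chemokines, 20 of 22 NF-kappaB members, 14 of 25 immediate early genes and 14 of 20 costimulation genes rose, or 15, 16, 20, 14 and 15 adjusted over the list alone (camera adjusted p = 2.4e-24, 2.2e-22, 3.4e-26, 1e-15 and 6.9e-17 in that order, and adjusted p = 0.0275, 0.0275, 0.0275, 0.0275 and 0.049 with an estimated correlation). Of the latter 3 lists 1 gene each fell (1 adjusted over the list alone). Of 38 interferon response genes, 12, 37 and 38 rose at 1, 2 and 6 h (11, 37 and 38 adjusted over the list alone). This list was called at each time (camera adjusted p = 9.8e-18, 1.9e-37 and 2.4e-33, and 0.175, 0.122 and 0.151 with an estimated correlation). At 6 h Ifit3, an antiviral protein, rose by 6.81 ± 0.92 and Irf7, an interferon-induced transcription factor, by 6.07 ± 0.84. At 6 h all 3 immunoproteasome genes rose (3 adjusted over the list alone, camera adjusted p = 0.00519, adjusted p = 0.173 with an estimated correlation). Psmb9 rose by 1.44 ± 0.27, and what was left of Psmb8 and Psmb10 by 0.37 ± 0.12 and 0.94 ± 0.28. Of 17 MHC class I presentation genes 13 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 2.6e-07, adjusted p = 0.173 with an estimated correlation). Of 28 cell cycle genes 11, 23 and 23 fell and 1, 1 and 1 rose (10, 23 and 23 and 1, 1 and 1 adjusted over the list alone). These were called down at 2 h (camera adjusted p = 0.0179, adjusted p = 0.711 with an estimated correlation) and 6 h (camera adjusted p = 0.0028, adjusted p = 0.631 with an estimated correlation).

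In dKO 649 genes rose and 4916 fell at 1 h, 1023 and 5998 at 2 h and 1635 and 6715 at 6 h, around medians of -0.41, -0.48 and -0.62. With median-of-ratios scaling 1422 rose and 1250 fell at 1 h, 2461 and 2064 at 2 h and 3537 and 3768 at 6 h. With the 5 libraries left out 1058 rose and 7563 fell at 1 h, 1544 and 8064 at 2 h and 2097 and 7643 at 6 h. Of the calls, 5554 of 5565, 6946 of 7021 and 8311 of 8350 were kept. At 1 h the count was 2811, 3046 and 2567 without dKO 0 h replicates 1, 3 and 4 in turn, and 2576 without dKO 1 h replicate 2. Across genes, which are not independent replicates, the dKO and WT responses correlated with Pearson's r of 0.927, 0.900 and 0.946 (Spearman's rho 0.871, 0.866 and 0.926) at 1, 2 and 6 h. Genes called in the same direction in both numbered 4517, 6539 and 7472, and 2, 2 and 17 were called in opposite directions.

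The last comparisons tested whether the LPS response itself differed between dKO and WT. At 1 h 4 genes passed, at 2 h 34 (15 with a higher and 19 with a lower response in dKO) and at 6 h 103 (64 and 39). Ifna1, a type I interferon, responded less in dKO at 1 h (-3.22 ± 0.24, limma adjusted p = 1.6e-09, 0.0479 against 4.49 RPKM at 1 h). Mul1, a mitochondrial ubiquitin ligase, also responded less (-1.35 ± 0.20, 3.48 against 12.1 RPKM at 1 h). At 2 h Bcl2l1, the survival factor Bcl-xL, responded less (-2.39 ± 0.48, 83.0 ± 54.7 against 300.3 ± 11.4 RPKM at 2 h), and so did Rhob, an endosomal GTPase (-2.14 ± 0.28). The change of Bcl2l1 was -1.17 without the 5 libraries, and its call was lost when WT 0 h replicate 4, WT 2 h replicate 3 or dKO 0 h replicate 2 was left out (limma adjusted p = 0.0525 to 0.0609). At 6 h the response of Ctsl was higher in dKO (1.07 ± 0.22, limma adjusted p = 0.00944), while Ece1, an endothelin-converting enzyme, fell further in dKO (-1.56 ± 0.26, 37.3 against 78.8 RPKM). Several genes with a higher response, such as Epcam (2.24 ± 0.28) and Tlr11 (2.19 ± 0.18), were near 0 in dKO at all times and fell in WT. At 6 h 62.1% of the calls were higher, and 45.3% with median-of-ratios scaling (48 higher, 58 lower). The counts without the 5 libraries were 201, 627 and 2263, with 4 of 4, 33 of 34 and 103 of 103 kept. The replicate numbers correlated across times within WT, and with a block on them within each genotype the counts were 4, 15 and 55. Single libraries moved these counts too. At 2 h the count was 20, 19, 21 and 14 without WT 0 h replicates 1 to 4 in turn and 15 without WT 2 h replicate 3. It was 18 without dKO 0 h replicate 2, and 57 and 164 without dKO 2 h replicates 1 and 3. At 6 h it was 63 and 60 without WT 0 h replicates 2 and 4, and 56 and 63 without WT 6 h replicates 1 and 4.

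Of the gene lists, 14, 10 and 8 were called for the difference in response at 1, 2 and 6 h. As labelled, only conventional dendritic cell markers were also called with an estimated correlation, shifted to a lower response in dKO at 1 h (camera adjusted p = 0.00145, adjusted p = 0.0438 with an estimated correlation) and 2 h (camera adjusted p = 0.000691, adjusted p = 0.032 with an estimated correlation). By limma 0 of their 14 members were called (1 and 2 adjusted over the list alone, 2 and 4 at unadjusted p below 0.05). The immediate early list shifted down at 1 h (camera adjusted p = 5.1e-12, adjusted p = 0.107 with an estimated correlation) and the cytokine list at 2 h (camera adjusted p = 2e-13, adjusted p = 0.135 with an estimated correlation). By limma 0 of 25 and 0 of 19 members passed (1 and 1 adjusted over the list alone, 6 and 10 at unadjusted p below 0.05). At 6 h the lysosome list shifted to a higher response in dKO (camera adjusted p = 2e-07, adjusted p = 0.515 with an estimated correlation), with 3 of 28 members called (5 adjusted over the list alone). So did the glycolysis list (camera adjusted p = 2.3e-05, adjusted p = 0.55 with an estimated correlation), with 1 of 22 called (1 adjusted over the list alone). The interferon response list did too (camera adjusted p = 0.00607, adjusted p = 0.902 with an estimated correlation), with 0 of 38 members passing limma (0 adjusted over the list alone, 2 at unadjusted p below 0.05). With the 5 libraries left out 37 of the 38 interferon genes passed at 6 h. Of the list calls 4 of 14, 0 of 10 and 5 of 8 were then kept in the same direction. The conventional dendritic cell markers were not called at 2 h (camera adjusted p = 0.352), and at 1 h not with an estimated correlation (camera adjusted p = 0.018, adjusted p = 0.231 with an estimated correlation). Neither the immediate early list at 1 h (camera adjusted p = 0.709) nor the cytokine list at 2 h (0.655) was then called.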

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

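Tests below that weigh an explanation, and comparisons with other splits of the libraries, were chosen after the result was seen, while the rules that picked out the values were planned.

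In 5 dKO libraries the LPS state lay nearest to another time than the label gives. In 4 of them many of the 465 named genes stood apart from the other 3 libraries of their group, where chance gives about 1 gene in 20. These numbered 126 genes in dKO 0 h replicate 2, 95 in dKO 1 h replicate 2, 50 in dKO 2 h replicate 2 and 105 in dKO 6 h replicate 4. An exchange with WT libraries is argued against by Psmb8, at most 7.42 RPKM in the 5 against at least 150.3 RPKM in WT. A faster or slower response of dKO cells is argued against because at most 1 library of any dKO group of 4 lay nearest to the same other time, with 11 of 16 at their own. An exchange of time labels within a replicate number stays open and may account for the pattern. The 3 libraries numbered 2 would take one another's times, as would the 2 numbered 4, which random reassignment gave with a probability of 0.0082. Only 3 of the 5 reached the correlations of the other dKO libraries with their own time (0.9716 to 0.9802). The libraries labelled dKO 2 h replicate 2 (0.9703) and dKO 2 h replicate 4 (0.9675) lay a little below that range. An exchange of labels therefore cannot be told apart from separate handling errors.

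Genes called at all 4 times with a mean change of at least 2-fold formed the next pattern, 173 without the targeted ones. In them WT and dKO ranges could lie far apart over 16 libraries each (Rpl3 36.6 to 66.2 against 0.342 to 2.63 RPKM, Rpl29 23.4 to 35.7 against 0.287 to 1.06, Gdpd3 0.734 to 4.13 against 43.0 to 69.7). DNA carried along beside the targeted genes is excluded as the whole cause, since 5.2% of them (9 of 173) lay within 5 Mb of a targeted gene, more than the 2.2% of all tested genes (245; Fisher's exact p = 0.014) but a small share. Reads of near-identical gene copies handled differently in the WT and dKO tables stay open, as only ribosomal protein genes were tested. Of these 79, only 2 changed 2-fold on average and the median was 0.05 (log2). DNA of another mouse strain elsewhere in the genome may contribute. Away from the targeted genes, 158 genes made 60 pairs of different families within 5 Mb bins, against a median of 40 in 10000 random sets (permutation p = 0.016). Neighbouring genes that are regulated together would cluster as well, and a direct effect of the missing subunits stays open as untested.

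Granulocyte markers were lower and several macrophage markers higher in dKO. Macrophage markers split, so more macrophages in dKO stay open. Of 13 abundant markers, 8 were higher on average over the 4 times (Pf4 1.55, Apoe 1.39, Lyz2 0.87, log2). The 4 lower were C1q genes (C1qb -2.15, C1qc -1.30, C1qa -1.12) and Emr1 (-0.21). Fewer eosinophils may account for part, as 5 of 7 abundant eosinophil markers were lower and 0 higher (Ear1 -1.68, Ear6 -1.29, Epx -1.27, Prg2 -1.06). For fewer neutrophils the markers cannot be told apart from a change within cells, since 3 of 8 were lower (S100a9 -1.58, Ltf -1.52, S100a8 -1.49), 1 was higher (Mmp8 1.04), and 6 of 8 were lower without the 5 libraries. Several of these genes are also expressed by dendritic cells or monocytes, and the labels name no sort that would remove other cells. A change of gene expression within dendritic cells stays open as untested.

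Single libraries also stood apart from the other 3 of their group. Aligned sequence did in WT 6 h replicate 4 (1.48 Gb). The number of genes at 1 RPKM or more did in WT 6 h replicate 3 (9581), dKO 0 h replicate 2 (9908), dKO 1 h replicate 2 (9269) and dKO 2 h replicate 2 (10481). Psmb8 did in WT 2 h replicate 4 (182 RPKM) and dKO 2 h replicate 4 (7.42 RPKM), and the spike-in share did in dKO 0 h replicate 4 (0.105%). Chance picks out about 1 group in 20. The unused spike-in controls took 0.224% (range 0.133 to 0.328) of aligned bases in WT and 0.112% (0.0943 to 0.127) in dKO libraries (n = 16 each). Library handling may differ with genotype, which the splits below cannot show.

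The test of the difference in LPS response passed 4 genes at 1 h, 34 at 2 h and 103 at 6 h (limma, 221, 2068 and 969 at unadjusted p below 0.05). At 1 h the response in dKO was higher for C77080 (1.37) and Tlr11 (1.36) and lower for Ifna1 (-3.22) and Mul1 (-1.35). At 2 h it was higher for Ppp1r3b (2.54), Tlr11 (2.12), C77080 (1.93), Vipr1 (1.79) and Rnase6 (1.75), and lower for Ifna1 (-3.05, listed at 0 in dKO), Ccl1 (-2.90), Il2 (-2.50), Bcl2l1 (-2.39) and Rhob (-2.14). At 6 h it was higher for Sept3 (2.45), Epcam (2.24), Tlr11 (2.19), Rnase6 (2.13) and Cd300e (2.00), and lower for Serpinc1 (-1.84), Fam131c (-1.78), Cd1d2 (-1.70), Tspan33 (-1.57) and Ece1 (-1.56). At 2 h leaving out any of 13 of the 16 libraries lost the call of Il2 (adjusted p up to 0.105). That of Rnase6 was lost with 9 (0.0924), Ccl1 with 7 (0.0762), Ppp1r3b with 5 (0.0706) and Bcl2l1 with 3 (0.0609), each including dKO 0 h replicate 2. Without the 5 the change was 1.63 for Ppp1r3b, -1.42 for Il2 and -1.17 for Bcl2l1.

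Splits of the same libraries into groups of the same sizes were compared with the real split. As many genes came from 1 of 35 splits, the real one, at all 4 times for dKO against WT (763, 1211, 1381 and 1649 genes against at most 1, 1, 161 and 0 in another split). The same was found at all 3 times for LPS in WT (5837, 8893 and 8457 against 1, 1 and 2) and at 6 h in dKO (8350 against 6266), so chance can be excluded there. In dKO the splits do not exclude it at 1 h (3 of 35 splits, 5565 against 5832) or at 2 h (2 of 35, 7021 against 8980). Each of the other splits that matched put dKO 0 h replicate 2, the library nearest to WT at 1 h, with the LPS group. Of the genes called in dKO, 4517 at 1 h and 6539 at 2 h were called in the same direction in WT, which shares no library with them, and 2 and 2 in the opposite one, so these splits do not speak against an LPS response. The 307 genes called at all 4 times were matched by 1 of 100 splits, the real one (highest other 0), and chance can be excluded. For the difference in response, chance is not taken as excluded at any time. At 1 h 4 of 100 splits reached the 4 genes (highest other 2328), which is a small share but rests on few genes, and 8 of 100 reached the 34 genes at 2 h (605) and 7 of 100 the 103 genes at 6 h (1406). Some of these splits called several times the real count, for reasons not tested. The numbers of gene lists called were matched too often to exclude chance in any comparison. They were matched in 8, 10, 5 and 20 of 35 splits for dKO against WT (16, 13, 18 and 8 lists against 17, 17, 19 and 14) and in 9, 14 and 8 of 35 for LPS in WT (15, 13 and 15 against 17, 21 and 18). For LPS in dKO it was 18, 10 and 24 of 35 (13, 15 and 13 against 17, 18 and 19), and 37, 79 and 93 of 100 for the difference in response (14, 10 and 8 against 20, 19 and 21).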

How the results depend on the processing

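The fit without the 5 dKO libraries was chosen after the result was seen, and every other alternative was planned. Counts moved with the 5 libraries, with the weight each library gets and with a fit of only the compared groups. Psmb8 and Psmb10 were lower in dKO under every alternative run. The 386 called changes of named genes between dKO and WT reversed under none of the alternatives, and neither did the 30 differences in response, while under median-of-ratios scaling 34 of 414 LPS changes in WT and 27 of 335 in dKO reversed, and 2 and 3 under quantile normalization. Few of those genes have values in the text. Without read counts, what depth limits could not be measured. Every alternative named before the data were examined was run, and the cause of the changes was not tested except where stated.

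Genes called are given for dKO against WT at 0, 1, 2 and 6 h, then LPS, then the difference in response. Leaving out the 5 libraries, they numbered 2920, 4368, 3689 and 5233, then 8888 and 8621 at 1 h in WT and dKO, then 201, 627 and 2263, and 1270 at all 4 times. Array weights, which weigh outlying libraries less, gave 3702, 4850, 2922 and 4818, then 9316 and 8914 at 1 h in WT and dKO, then 308, 452 and 2320, and 1357 at all 4 times. A fit of only the compared groups, with fewer libraries, gave 2267 at 1 h and 189 at 2 h for dKO against WT, 9091 at 1 h in WT, 2445 at 1 h and 0 at 2 h in dKO (limma, 2997 at unadjusted p below 0.05), 4 at 2 h and 164 at 6 h for the difference in response, and 126 at all 4 times. Median-of-ratios scaling gave 3151 at 1 h in WT, 2672 and 4525 at 1 and 2 h in dKO, and 55 at 2 h for the difference. Quantile normalization gave 2109 at 2 h for dKO against WT, 2979 and 4522 at 1 and 2 h in dKO, and 79 at 2 h for the difference. The stricter filter, which tests fewer genes, gave 472 at 0 h for dKO against WT and 1, 21 and 68 for the difference, and no filter gave 16, 80 and 187 for the difference. A pseudocount of 0.1 gave 2 at 1 h and 21 at 2 h for the difference, and a pseudocount of 1 gave 60 at 2 h. The replicate block gave 15 at 2 h and 55 at 6 h for the difference. All other counts, and all counts without the intensity trend, lay within 1.5 times those reported.

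With single libraries left out in turn, the counts ranged from 506 to 711, 835 to 1080, 969 to 2247 and 1093 to 1665 for dKO against WT. They ranged from 4655 to 5126, 8568 to 8660 and 8072 to 8139 for LPS in WT, from 2567 to 7072, 4768 to 8627 and 7739 to 8958 in dKO, were 4 throughout at 1 h for the difference, and ranged from 14 to 164 and 56 to 116 at 2 and 6 h, and from 248 to 454 at all 4 times. The log2 change of Psmb8 ranged from -5.46 to -5.39, -5.49 to -5.26, -5.07 to -4.86 and -5.75 to -5.65 at 0, 1, 2 and 6 h, and that of Psmb10 from -3.46 to -2.95, -3.48 to -3.30, -2.97 to -2.51 and -3.50 to -3.06.

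Of 171 list calls, 94 held with fry and 29 with a correlation estimated from all libraries. Without the 5 its adjusted p moved both ways (LPS at 2 h in WT, interferon genes 0.0967 to 0.0121, neutrophil markers 0.0967 to 0.224). Held in the same direction were 169 and 170 with pseudocounts of 0.1 and 1, 159 with no filter, 153 of 161 with the stricter filter, 143 with median-of-ratios scaling, 143 with quantile normalization, 171 with the replicate block and 125 without the 5 libraries. Without the 5, the mean change turned for NF-kappaB members at 0 h (-0.17) and chemokines at 2 h (0.30) between dKO and WT, and for the response of chemokines at 2 h (0.32).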

Other observations

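The values of this paragraph come from the fit without the 5 dKO libraries nearest to another time, chosen after the data were seen. Type I interferon response genes, which defend cells against viruses, then stood lower in resting dKO cells. At 0 h 35 of 38 were lower than in WT (camera adjusted p = 8.3e-27, adjusted p = 0.0759 with an estimated correlation). At 1 h 26 were lower and 6 higher (9.1e-05, adjusted p = 0.431 with an estimated correlation), and at 2 h 18 were lower and 3 higher (camera adjusted p = 0.0528). After 6 h of LPS the direction was the other way, with 14 of 38 higher and 0 lower (4.4e-05, adjusted p = 0.708 with an estimated correlation). The response of 10, 24 and 37 of these 38 genes to LPS was higher in dKO than in WT at 1, 2 and 6 h (camera adjusted p = 5.5e-19, 4.6e-29 and 1.5e-39). With an estimated correlation the adjusted p was 0.231, 0.113 and 0.0314. Toll-like receptor signalling genes at 6 h had 14 of 27 higher and 6 lower in dKO (camera adjusted p = 9.4e-05, adjusted p = 0.0151 with an estimated correlation).

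In all libraries as labelled, Nnt, a mitochondrial transhydrogenase chosen after its values were seen, was called higher in dKO at all 4 times (limma, mean log2 change 1.31). Over the times it ranged from 0.476 to 2.67 RPKM in the 16 WT libraries and from 1.23 to 7.86 RPKM in the 16 dKO libraries.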
